A study of Homo sapiens with 12 samples.

How the data were processed

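Chromatin accessibility had been measured in 12 libraries of lineage-depleted cells from 4 patients with B-cell acute lymphoblastic leukemia, with 3 technical replicates per patient. Patients 1, 2 and 4 gave bone marrow and patient 3 gave mononuclear cells of the blood, per the labels. Cells were permeabilised and transposed together under the Fast-ATAC protocol, and the purified DNA was amplified and sequenced, per the labels' protocols. The submitters' processing notes name bcl2fastq, FastQC, Bowtie2, Picard and MACS2, without versions, and both the hg38 and the hg19 build. Read trimming, duplicate removal, any shift of reads for the transposase and the peak threshold are not given in the sources used here.

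The deposited values were a summit list per library. Each row of the authors' lists held a position and a score, which MACS2 writes as −log10 of a p-value or q-value; which of these it was is not given in the sources used here. Summits had been called in each library on its own, and a peak held 1.49 to 1.83 summits on average. The lowest score in a list lay between 2.03 and 2.49. The lists hold no read counts, so sequencing depth is unknown and no counting interval could be given. Because a score depends on depth, the main calls used scores only to rank summits within their own list. Median and lowest scores are given to describe the lists, and an alternative applied a fixed score of 20 to every list.

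The build of the lists was checked against chromosome lengths. No summit lay past the end of an autosome of hg19 (0 of 22), whereas 14 of 22 autosomes had summits past their end in hg38. All coordinates are therefore given in hg19, counted from 1. The gene table at hand is of the GRCh38.p14 assembly, so none of its coordinates were used, none were converted, and no region could be given a gene name. For this reason 5 planned analyses were not run: the distribution over promoters, exons, introns and intergenic sequence; the genes that differ between patients; the 23 fixed gene lists; their enrichment in patient-specific regions; and the 24 fixed motifs, which need the genome sequence. The planned rule for named genes was replaced, after the files had been seen, by the same rule applied to 100 kb windows, and positions were described by cytoband. Cytobands and their Giemsa stain class came from the hg19 table of the R package circlize 0.4.16, and chromosome lengths from GenomeInfoDb 1.38.1.

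Only the 22 autosomes were analysed. Summits closer than 501 bp were collapsed to the highest-scoring of them, and the 50000 highest-scoring collapsed summits of a library were called its strong summits, so that every library entered with the same list length. A strong summit was shared when the other library had a strong summit within 250 bp, and sharing was expressed as the Jaccard index. Consensus regions were built over all libraries by keeping summits in order of their score quantile within the library and removing those that overlapped. A region was specific to a patient when it was strong in 3 of 3 libraries of that patient and had no summit within 250 bp among the 100000 highest-scoring summits of any of the 9 other libraries. A region was lacking in a patient when it was strong in all 9 other libraries and had no such summit in the 3 libraries of that patient.

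Sharing was tested with an exact permutation test over all 15400 partitions of the 12 libraries into 4 sets of 3, one-sided for the mean index within sets minus that between sets. The smallest p that this test can give is 6.49e-05. Strong summits were counted in 100 kb windows holding at least 3 over the 12 libraries. Each of 13540 windows was tested over the same partitions with the between-patient sum of squares, with Benjamini-Hochberg adjustment and a threshold of 0.05. A patient was called high or low in a window past the threshold when its 3 libraries all lay above or below the 9 others. The text takes up to 4 high and 2 low windows per patient with the largest gap between the nearest libraries, leaving out neighbouring windows, and up to 3 windows per patient with the most specific regions. The sharing test and the specific and lacking calls, with their list lengths and distances, were fixed before the data were examined. The windows, bands, the distance of 12.5 kb to the next strong summit, clustering and the tests used for them were chosen after the files had been seen, and the exact band test after its first results. A distance of 10 kb was tried as well.

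Giemsa-negative shares of patient-specific regions were compared with those of the patient's other regions by an exact conditional test that permutes bands within chromosomes, two-sided, with Mantel-Haenszel odds ratios and their 95% intervals. Clustering was compared with 1000 draws of the same number of the patient's other regions per chromosome. Both families were adjusted over specific and lacking regions of all patients. Regions are not replicates of a patient, so these tests compare sets of regions. The band test counts regions as independent, although neighbouring regions often share a band, so its p-values are likely too small and its intervals too narrow. Neither background was matched for rank. Replicates are technical, so every p-value across libraries measures differences between 4 patients against the spread between library preparations only.

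The calls were tested on simulated data. All of 180 specific regions planted in patient 2 were recovered. The other patients were not simulated. Real specific regions of patient 2 stood at a median rank of 36336 ± 264 (SD, n = 3), and recovery was not tested by rank. The recovery of planted regions thus gives no sensitivity for real specific regions, which stood low in the lists. The window test made 0 calls of 200 changed windows, at 2-fold or 4-fold in 1 patient, when only these among 13540 windows were changed, although 100% of them had an unadjusted p under 0.05. In this and the next simulation, all changed windows had a mean count at or above the median, so recovery in sparser windows is unknown. When 6105 such windows were changed, the window test recovered 98.0% at 2-fold and 100% at 4-fold, with 17 false calls. The adjusted test thus finds changes in 1 patient only where many windows change, and a window count cannot be compared between settings with different shares of changed windows. Alternatives covered list length, a fixed score, the sharing distance, window size, the absence side, equal numbers of summits per chromosome, equal window totals per chromosome arm, each library left out, patient 1 left out and the replicate number as a block. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9.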

Results

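Open chromatin was compared between 4 patients with B-cell acute lymphoblastic leukemia, a cancer of immature B-lineage cells. Fast-ATAC marks open chromatin with a transposase that inserts sequencing adapters into accessible DNA. Each patient contributed 3 technical replicate libraries of lineage-depleted cells, from bone marrow in patients 1, 2 and 4 and from blood in patient 3. The values are the authors' summits, the points of highest signal within called peaks, with a score on the −log10 scale. Read depth is unknown, because the lists carry no read counts.

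The lists differed in length between patients. On the autosomes patient 1 had 485163 ± 70244 summits (SD, n = 3), patient 2 had 341622 ± 5097, patient 3 had 281187 ± 18931 and patient 4 had 318105 ± 31246. Scores describe each list, since a common scale between lists is not established. The median score was 5.34 ± 0.25 (SD, n = 3) in patient 1, against 9.44 ± 1.26, 11.2 ± 1.94 and 10.5 ± 0.70 in patients 2, 3 and 4. Among summits ranked beyond 100000 and up to 150000, 17.8% ± 1.2 (SD, n = 3) recurred in both other libraries of patient 1. The corresponding shares were 37.6% ± 0.22 in patient 2, 34.7% ± 0.24 in patient 3 and 32.3% ± 0.92 in patient 4. Presence in the main comparisons was read from the 50000 highest-scoring summits of each library, called strong summits, and absence from the 100000 highest-scoring. The lowest score among strong summits was 24.1 ± 5.2 (SD, n = 3) in patient 1, against 61.6 ± 8.8, 58.2 ± 5.3 and 62.2 ± 14.8 in patients 2, 3 and 4. Strong thus refers to rank within a list, and lists of equal length differed in score.

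The first comparison asked whether libraries of the same patient share more open regions than libraries of different patients. Replicates shared most of their strong summits, with a mean Jaccard index of 0.826 within patients against 0.540 between patients. The lowest index within a patient, 0.741, lay above the highest between patients, 0.578. The difference of means was 0.287, and none of the other partitions of the 12 libraries into 4 sets of 3 gave one as large (one-sided exact permutation p = 6.49e-05, the smallest that 15400 partitions can give). With all deposited summits the difference was 0.154. Within patients the index was 0.754 ± 0.017 (SD over 3 library pairs) in patient 1, 0.852 ± 0.0050 in patient 2, 0.854 ± 0.0031 in patient 3 and 0.846 ± 0.0073 in patient 4. Between patients, patients 1 and 4 shared most (0.567 ± 0.0081, SD over 9 library pairs), followed by patients 2 and 3 (0.562 ± 0.0016). Patients 1 and 3 shared least (0.508 ± 0.0059), close to patients 3 and 4 (0.511 ± 0.0015).

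**Figure D1:**
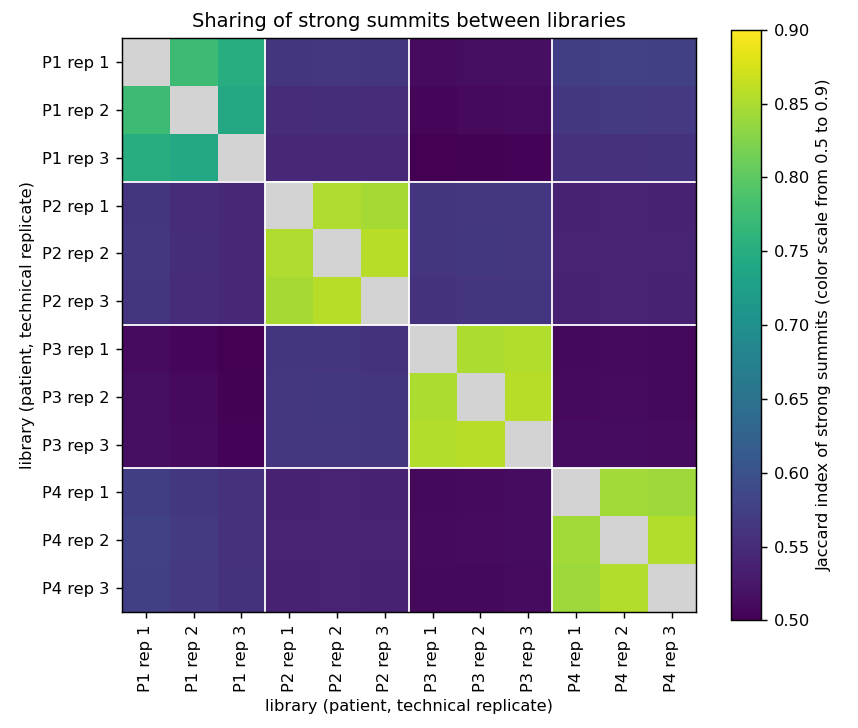
Jaccard index of strong summits for every pair of the 12 libraries, ordered by patient and technical replicate on both axes, with the index as color from 0.5 to 0.9 and each library's comparison with itself in grey. The blocks of 3 libraries on the diagonal lie at 0.741 or above and all other pairs at 0.578 or below.

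Most repeatable regions were open in more than 1 patient: of 67320 regions strong in 3 of 3 libraries of at least 1 patient, 22397 were so in exactly 1. The 12 libraries gave 85625 consensus regions, of which 23405 (27.3%) were strong in every library and 8868 (10.4%) in a single library. Regions strong in all 12 libraries stood high in each list, with a median rank of 13962 ± 3.2 (SD, n = 3) in patient 1 and 14653 ± 37 in patient 3. Patient-specific regions stood lower, at a median rank of 32989 ± 560 in patient 1, 36336 ± 264 in patient 2, 35474 ± 517 in patient 3 and 37733 ± 223 in patient 4. Among regions strong in exactly 2 patients and absent from the rest, 389 belonged to patients 2 and 3 and 323 to patients 1 and 4. The other pairs had 183 (patients 1 and 2), 113 (patients 1 and 3), 104 (patients 3 and 4) and 75 (patients 2 and 4).

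The second comparison asked which regions were open in 1 patient alone. Patient 3 had 1425 specific regions, patient 2 had 935, patient 4 had 684 and patient 1 had 479. These were 3.30%, 2.17%, 1.59% and 1.22% of the regions strong in 3 of 3 libraries of the patient. The order of the patients depended on the lists: with absence asked of all deposited summits, patient 2 had 313, patient 3 had 297, patient 4 had 165 and patient 1 had 124. Most specific regions of each patient thus had a lower-ranked summit in a library of another patient, and were not shown to be closed there. With all deposited summits as strong, patient 1 led with 12568.

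**Figure D2:**
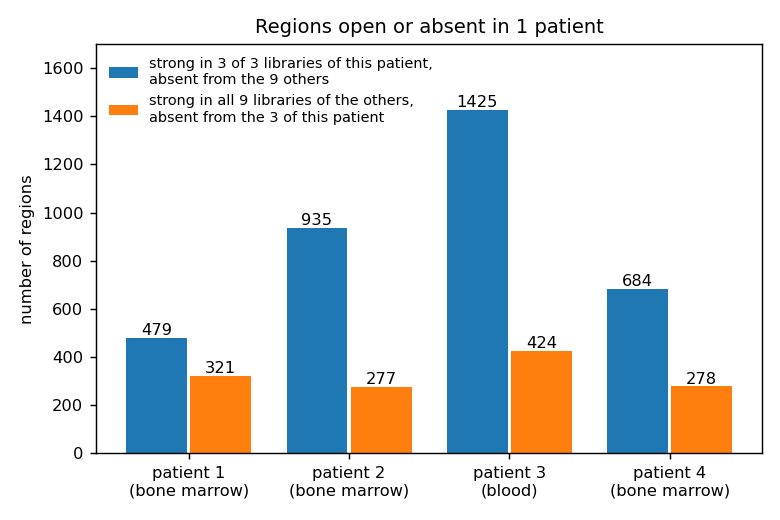
Number of regions strong in all 3 libraries of a patient and absent from the 9 others (blue), and strong in all 9 others and absent from the 3 of the patient (orange). Specific regions range from 479 in patient 1 to 1425 in patient 3, and lacking regions from 277 in patient 2 to 424 in patient 3.

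Specific regions lay close together on the chromosomes, and windows holding the most of them are given for each patient. A region can be specific to only 1 patient, and the windows were picked by their number of specific regions. Different loci and higher counts in the patient thus follow in part from the choice. In patient 2, the window of chromosome 7 from 27200001 to 27300000 (band 7p15.2) held 11 specific regions, with 21.7 ± 0.58 strong summits (SD, n = 3) against 2 to 3 in the 9 other libraries. Band 10q21.3 (chromosome 10, 65200001 to 65300000) held 8, with 18 ± 2.0 strong summits against 4 to 6. Band 20p12.2 (chromosome 20, 9400001 to 9500000) also held 8, with 10.3 ± 1.5 strong summits against 0 in every other library. In patient 3, 10 specific regions lay in 7q36.3 (chromosome 7, 158800001 to 158900000), with 15.7 ± 0.58 strong summits against 0 to 1. Another 10 lay in 15q11.2 (chromosome 15, 22900001 to 23000000), with 18.3 ± 0.58 against 1 to 4. In patient 4, 8 lay in 3p22.3 (chromosome 3, 32400001 to 32500000), with 43.3 ± 1.2 strong summits against 8 to 14, and 7 lay in 3q26.2 (chromosome 3, 169300001 to 169400000), with 13.7 ± 0.58 against 0 to 2. In patient 1, 8 lay in 17q11.2 (chromosome 17, 27400001 to 27500000), with 33 ± 1.0 against 17 to 24, and 7 in 8q24.3 (chromosome 8, 142100001 to 142200000), with 44.3 ± 3.8 against 19 to 27.

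Specific regions were set against the other repeatable regions of the same patient by chromosome band. The patients' specific regions were not tested against each other. Specific regions stood lower in the lists, at a median rank of 32989 to 37733 against 20808 to 22818 for all repeatable regions. The comparison was not matched for rank, so rank and patient specificity were not separated. Each region also counts as independent in the test. However, 34.9% to 49.8% of specific regions lay within 100 kb of another, so the p-values are likely too small and the intervals too narrow. Giemsa-negative bands, the light bands of stained chromosomes, held 81.8% of the specific regions of patient 1 against 68.2% of its other repeatable regions (odds ratio 2.01, 95% interval 1.59 to 2.55, adjusted p = 4.44e-09, two-sided exact conditional test within chromosomes). By the same exact test the share was lower than in the background in patient 2 (56.7% against 66.6%, odds ratio 0.641, adjusted p = 3.2e-10), patient 3 (63.3% against 67.3%, odds ratio 0.795, adjusted p = 0.000166) and patient 4 (58.6% against 66.1%, odds ratio 0.731, adjusted p = 0.000195). Taken over all strong summits, 68.5% ± 0.30 (SD, n = 3) of those in patient 1 lay in Giemsa-negative bands, against 66.2% ± 0.016, 67.1% ± 0.019 and 65.8% ± 0.037 in patients 2, 3 and 4. For any difference among the 4 patients, the exact permutation test gave p = 6.49e-05 (adjusted p = 0.00013). Patient 1 alone was not tested against the others in this share. With all deposited summits in place of strong summits both differences turned around in patient 1, to −5.74 percentage points for its specific regions minus their background and −0.630 for all its summits minus those of the others. With 25000 strong summits, which left 97, 272 and 92 specific regions in patients 1, 3 and 4, the exact test no longer passed the threshold in any of these patients. The difference there was 12.8 percentage points in patient 1 (adjusted p = 0.0707, exact test; 13.7 with 50000), 0.888 in patient 3 (adjusted p = 1) and −3.24 in patient 4 (adjusted p = 0.955). Without patient 1, the difference in patient 2 was −3.67 percentage points, against −9.88 with all libraries. The calls also ended for patient 3 without patient 1 (0.168, adjusted p = 0.363, exact test) and for patient 4 with absence from all deposited summits (−3.56, adjusted p = 0.320). Other settings widened the difference in patient 3 from −4.00. It was −8.11 with 100000 strong summits, −11.5 with all deposited summits and −11.0 with absence from all deposited summits.

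The mirror comparison counted regions strong in every other patient and absent from the 100000 highest-scoring summits of each library of 1. There were 424 in patient 3, 321 in patient 1, 278 in patient 4 and 277 in patient 2. The order depended on the lists: patient 1 came first with 869 against 751 in patient 3 with 100000 strong summits, and with 1211 against 842 at a score of at least 20. Without patient 1, 1124 regions were lacking in patient 4, 758 in patient 3 and 636 in patient 2. The regions lacking in patient 1 were less often Giemsa-negative than their background (59.8% against 66.8%, odds ratio 0.719, adjusted p = 0.00696, exact conditional test), a call that ended with 25000 strong summits (adjusted p = 0.955). The same exact test did not pass the threshold in patient 2 (adjusted p = 0.634), patient 3 (adjusted p = 0.752) or patient 4 (adjusted p = 0.0787). These comparisons depended on the setting. Patient 4 passed the exact test without replicate 1 or replicate 2 of patient 1 (adjusted p = 0.0466 and 0.0286), and patients 2, 3 and 4 each passed it under other lists, patient 3 in the opposite direction.

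The third comparison located the loci where strong summits were denser or sparser in 1 patient. Of 13540 windows of 100 kb, 8595 (63.5%) differed between patients by the exact permutation test, and 6443 had at least 1 patient apart from the 9 libraries of the others. Patient 1 was high in 737 windows and low in 701, patient 2 high in 1251 and low in 547, patient 3 high in 1354 and low in 809, and patient 4 high in 1332 and low in 717. The median count per window and library was 2, which leaves low calls less room than high calls. The balance of high and low calls is therefore not a trait of the patients alone. With window counts scaled to equal totals per chromosome arm, 10551 windows differed, and low calls rose to 1106, 1186, 1555 and 1458 in patients 1, 2, 3 and 4, with 1452, 1913, 2074 and 2193 high calls. Such scaling turns equal counts into unequal values wherever arm totals differ between libraries. How far this alone raised the calls was not tested. If the 12 libraries were exchangeable and without ties, 3 given libraries would lie at 1 end in 0.455% of windows. Technical replicates resemble each other and the calls also required the threshold. An excess over this share thus shows no more than that resemblance. The split into high and low calls followed the choice of list: in patient 1, 51.3% of calls were high with equal list lengths, 96.7% with all deposited summits and 4.31% at a score of at least 20. High calls went from 62.6% to 19.8% in patient 3 and from 65.0% to 34.7% in patient 4 with all deposited summits, and in patient 2 from 69.6% to 92.3% at a score of at least 20. Without patient 1, where 280 partitions remain, 1682 windows differed, and 49.1%, 50.9% and 49.8% of calls were high in patients 2, 3 and 4. Each of these windows had 1 high and 1 low patient, so the split over these patients is even by construction.

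Named windows were those with the widest gaps within each patient and direction. Patient 1 was high in 8q24.3 (chromosome 8, 145500001 to 145600000), with 40 ± 2.6 strong summits (SD, n = 3) against 8 to 16 in the 9 other libraries. It was also high in 8p21.3 (chromosome 8, 22500001 to 22600000), with 36 ± 3.0 against 11 to 13, and low in 17q22 (chromosome 17, 55500001 to 55600000), with 9.33 ± 2.1 against 21 to 30. Patient 2 was high in 19p13.11 (chromosome 19, 18300001 to 18400000), with 61.3 ± 2.1 against 18 to 41, and in 11q24.1 (chromosome 11, 122900001 to 123000000), with 22 ± 1.0 against 5 to 10, a difference of means of 15.4 that fell to 0.778 with 25000 strong summits, where the call ended. It was low in 2p25.3 (chromosome 2, 1700001 to 1800000), with 5 ± 1.0 against 18 to 24. Patient 3 was high in 22q11.22 (chromosome 22, 23200001 to 23300000), with 44.3 ± 1.5 against 6 to 22, and in 11p15.4 (chromosome 11, 2800001 to 2900000), with 24 ± 0 against 5 to 8. It was low in 17q25.1 (chromosome 17, 72700001 to 72800000), with 14.3 ± 0.58 against 21 to 29. Patient 4 was high in 3p22.3, as above, and in 18p11.21 (chromosome 18, 13400001 to 13500000), with 35.7 ± 1.5 against 5 to 16. It was low in 19p13.3 (chromosome 19, 2200001 to 2300000), with 15.7 ± 0.58 against 29 to 41; without patient 1 this call ended while the difference stayed at −14.8, from −17.3. The window 5q31.1 (chromosome 5, 131700001 to 131800000) set patients apart in both directions, with 15.7 ± 1.2 strong summits in patient 3, 23.3 ± 0.58 in patient 1, 23.7 ± 1.2 in patient 2 and 40.7 ± 0.58 in patient 4. Adjusted p over the 24 calls, made in 23 windows, ranged from 0.00283 to 0.0297 in the exact permutation test.

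**Figure D3:**
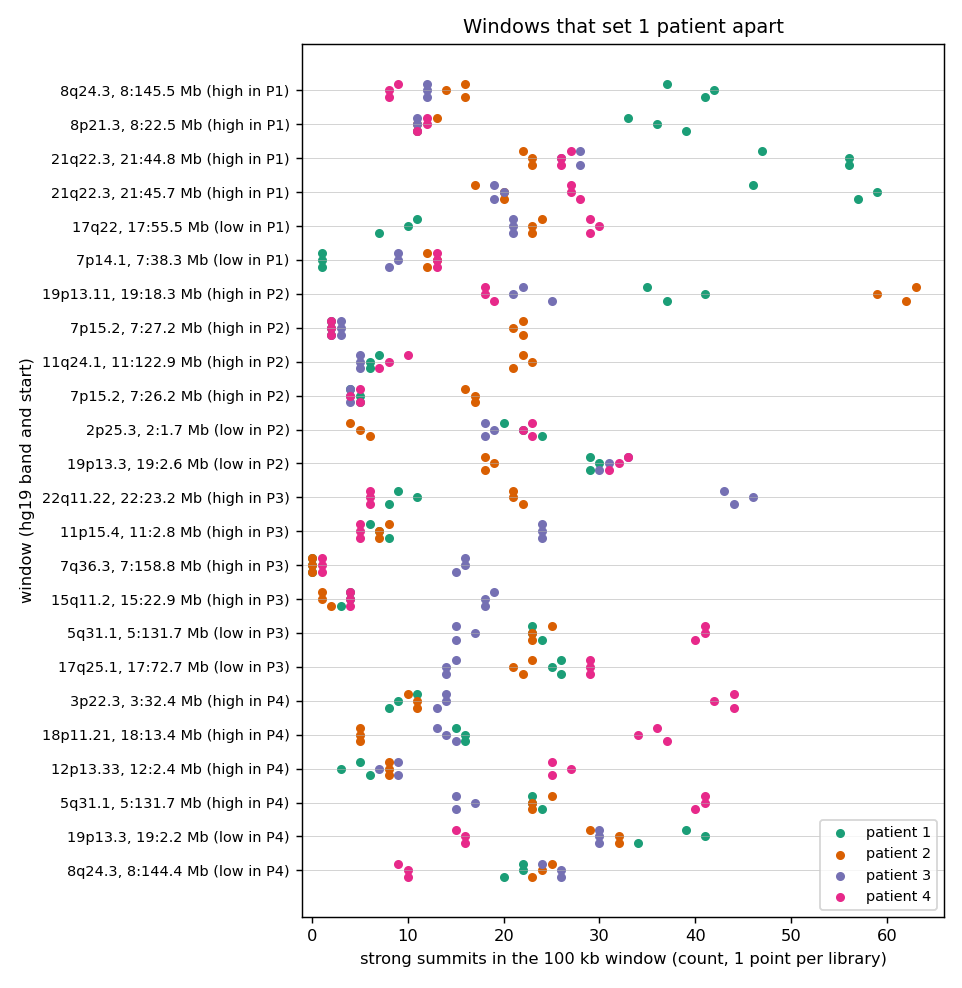
Strong summits per library, as a count on the horizontal axis, for 24 calls in 23 windows of 100 kb, up to 4 high and 2 low per patient by widest gap, listed by hg19 band and start with the patient set apart; each point is a library, colored by patient. In every row the 3 libraries of the named patient lie on 1 side of the 9 others, for example at a mean of 43.3 against 8 to 14 in 3p22.3.

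Strong summits of patient 1 were also more closely spaced than those of the other patients. The share with the next strong summit within the set distance was 62.9% ± 0.42 (SD, n = 3) in patient 1, 58.5% ± 0.17 in patient 2, 60.4% ± 0.14 in patient 3 and 60.5% ± 0.33 in patient 4. An exact permutation test of any difference among the 4 patients gave p = 0.00039. Patient 1 alone was not tested against the others. At a score of at least 20, which leaves patient 1 the shortest lists, the difference turned around, to −3.27 percentage points for patient 1 minus the others.

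Tissue could not be tested, because blood came from patient 3 alone. The mean Jaccard index was 0.527 between patient 3 and the 3 marrow patients and 0.553 among the marrow patients. The mean index to the remaining patients was 0.543 for patient 1, 0.551 for patient 2 and 0.538 for patient 4.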

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

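The tests of copy number, the absence side, tissue, depth and other sets of 3 libraries were chosen after the results were seen; the test of background in patient 1 and the count of called windows in other partitions were not, but the unadjusted count was. Over the 12 libraries, 15760 summits (0.356% of all) lay on unplaced or alternative contigs, which no comparison used; they were picked out because they lie above the 3 that a count of 0 allows.

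Of 100 partitions of the libraries, 1 (the real partition) gave 8595 windows or more, and the highest of the others gave 0. The adjusted test makes no calls where few windows separate the sets, so the count at an unadjusted p under 0.05 is given too. It was 9291 for the patients and at most 2379 for the others. Every other partition puts technical replicates of a patient in different sets. The counts thus show only that replicates resemble each other more than libraries of other patients. Unequal numbers of summits per whole chromosome did not account for most of the calls. With the same number of strong summits per chromosome in every library, 83.9% of the called windows (7213) still passed the threshold. Equal numbers per whole chromosome do not even out changes of an arm or a segment. Gains or losses of chromosome arms or segments, and library preparation, which the labels do not separate from patient, stay open.

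The long, low-scoring lists of patient 1 may reflect more background. Its weak summits recurred in both other libraries in 17.8% of cases, and no library of another patient fell below 31.3%. The highest index of sharing between libraries of patient 1 was 0.774, below the lowest of 0.841 within another patient. This goes against greater depth alone only if deeper libraries rank their strong summits with less noise. That was assumed and not tested, and depth is unknown, so greater depth is not excluded. GC content was not tested, and no biological explanation was tested.

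Patient 3 had the most specific regions, and this first place may rest on the absence side of the call. With absence asked of all deposited summits, patient 3 had 0.949 times the count of the highest other patient (297 against 313). Those lists differ in length and were shortest on average in patient 3, so absence and list length are not separated. Patient 3 kept first place with 25000 or 100000 strong summits and at a score of at least 20. Patient 1 led with all deposited summits as strong. Unequal numbers of summits per whole chromosome did not account for this first place. With equal numbers per chromosome patient 3 still had 1.61 times the next count (1385 against 858). Changes of an arm or a segment were not tested for these regions. Blood and patient cannot be told apart, because only 1 patient gave blood. Of 220 sets of 3 libraries, 4, 2, 1 and 3 reached the counts of 479, 935, 1425 and 684 in patients 1, 2, 3 and 4, and the highest of the sets that mix patients gave 7. A mixed set must lack its regions in technical replicates of its own members, so these counts say no more than that replicates resemble each other.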

How the results depend on the processing

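All alternatives on windows, bands, clustering and spacing were chosen after seeing the data, as were, for every result, equal numbers per chromosome and leaving out patient 1. The sharing difference kept its direction and its side of the threshold in every setting run, at 0.154 with all deposited summits, 0.279 to 0.302 with each library left out and 0.314 without patient 1. Counts of specific regions are given for patients 1, 2, 3 and 4 in that order. With 25000 strong summits they were 97, 131, 272 and 92; with all deposited summits 12568, 7231, 5060 and 4882; with absence from all deposited summits 124, 313, 297 and 165. With 100000 strong summits patients 2, 3 and 4 had 2294, 2455 and 1945, and at a score of at least 20 they had 3640, 4316 and 3172. Asking for at least 2 of 3 libraries gave 915 in patient 1. Without patient 1, patients 2 and 4 had 1584 and 1801. Lacking regions numbered 107, 62, 107 and 68 with 25000 strong summits; 1875, 946, 2533 and 1590 with all deposited summits; and 1211, 472, 842 and 441 at a score of at least 20. With 100000 strong summits patients 1 and 3 lacked 869 and 751. Without patient 1, patients 2, 3 and 4 lacked 636, 758 and 1124. With each library left out, specific regions ranged over 492 to 682, 946 to 1022, 1456 to 1578 and 700 to 817, and lacking regions over 327 to 442, 284 to 336, 435 to 519 and 285 to 353. Windows that differ numbered 5708 with 25000 strong summits, 15638 with all deposited summits, 1682 without patient 1 and 8121 to 8874 with each library left out. Patient labels permuted within replicate number (replicate block, 576 partitions) gave 3777 windows, with sharing p = 0.00174 in the exact permutation test, the smallest it can give. The numbers are not shown to pair libraries: libraries with the same number deviated together with a mean correlation of -0.0035, and 3 of 12 lay closest to their own number. The Giemsa-negative share of patient 1 minus the others was 1.05 with 25000 and 3.94 with 100000 strong summits against 2.13, turned to -0.630 with all deposited summits and ranged from 1.99 to 2.29 with each library left out. It has no value without patient 1. The closer spacing in patient 1 turned to -3.27 percentage points at a score of at least 20, where the lists of patient 1 are shortest, and was 3.30 at 10 kb and 2.96 to 3.38 with each library left out. The Giemsa-negative share of specific regions minus background turned to -5.74 in patient 1 with all deposited summits, and in patient 3 to 0.888 with 25000 strong summits and 0.168 without patient 1. For lacking regions, not past the threshold at first in patients 2, 3 and 4, it turned to -3.69 in patient 2 and -3.49 in patient 4 with 25000 strong summits. In patient 3 it turned to -2.56 with 100000 strong summits, -3.33 with all deposited summits, -2.26 at a score of at least 20, -2.65 for sharing within 500 bp, -0.775 with equal numbers per chromosome, -4.03 without patient 1, and ranged from -0.214 (without patient 3 replicate 1) to 2.25 with each library left out. Lacking regions passed the threshold in patients 2 and 4 with all deposited summits (3.55 and 3.15) and at a score of at least 20 (5.91 and 6.94), in patient 4 for sharing within 500 bp (9.28), and in patient 3, turned around, with all deposited summits and without patient 1. The clustering of specific regions in patient 1 turned to -0.673 percentage points against the mean draw with all deposited summits. The share of high window calls in patients 2, 3 and 4 was 69.6%, 62.6% and 65.0%, against 68.9%, 19.8% and 34.7% with all deposited summits, 92.3%, 79.5% and 89.1% at a score of at least 20, and 49.1%, 50.9% and 49.8% without patient 1. Under the block it was 54.7% in patient 2. Library separation was not rechecked: 489 of 498 alternative differences of named windows kept sign and threshold, 9 lost the threshold and 0 reversed. With 25000 strong summits 11q24.1 and 7p15.2 (26200001 to 26300000) lost it in patient 2, each at 0.778. Under the block 8p21.3 in patient 1 and 7p15.2 lost it at unchanged 24.6 and 12.2. The other 5 lost it without patient 1, at 12.3 (7p15.2) and -13.3 (19p13.3, 2600001 to 2700000) in patient 2. Patient 4 had 17.5 (12p13.33), -14.8 (19p13.3, 2200001 to 2300000) and -15.0 (8q24.3). Shorter lists and fewer partitions lower the counts by construction; the cause was not tested for the other changes. The planned analyses of annotation classes, genes, gene lists and motifs were not run, with their alternatives, because no hg19 annotation or sequence was used here. Unknown read depth limits statements on absence, since a shallow library can miss a region.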

Other observations

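The tests of clustering and bands were chosen after the files had been seen, although what clustering would show was written before its result. A hypothesis was that patient-specific regions come in groups along the chromosomes. In 4 of 4 patients, more specific regions had another specific region of the same patient within 100 kb than in any of 1000 draws of its other repeatable regions. The draws kept the numbers per chromosome but were not matched for rank, and specific regions stood lower in the lists. The share was 44.3% in patient 1 (highest draw 27.1%), 34.9% in patient 2 (25.7%), 49.8% in patient 3 (36.8%) and 41.2% in patient 4 (28.1%), with p = 0.001, the smallest that these draws can give in a permutation test. Regions lacking in a patient also lay above the highest draw, with 22.1% in patient 1 (highest draw 17.8%), 28.9% in patient 2 (15.9%), 19.1% in patient 3 (17.2%) and 29.5% in patient 4 (16.5%). With all deposited summits both calls ended in patient 1, with an excess over the mean draw of -0.673 percentage points for specific regions and 1.36 for lacking regions (from 12.8). The excess for specific regions fell to 1.70 in patient 2 (from 14.5), 2.23 in patient 3 (from 18.8) and 10.7 in patient 4 (from 19.8). At a score of at least 20 it was 5.97 in patient 2 and 6.32 in patient 3, so its size rests on the lists. The excess for lacking regions was 6.65 in patient 1 without its replicate 1, and in patient 3 it lost its call with 25000 strong summits, at 4.13. Groups of regions may follow from regulation of whole loci or from altered chromosome segments, which 4 positive tests of 4 do not separate.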
